A study of Mus musculus with 8 samples.

How the data were processed

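The series holds 8 mouse libraries, 3 control and 3 knockout RNA libraries and 1 control and 1 knockout ChIP library, all from primary hepatocytes given 100 nM glucagon for 12 h. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the numbered libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom from 7.01 (control replicates 2 and 3) to 140.5 (control replicates 1 and 2).

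The deposited RNA table holds whole-number counts per Ensembl gene with gene positions on mm10, made with HISAT2 2.1.0, Bowtie2 2.2.3 and HTSeq 0.6.0 per the submitters' processing notes. The role of each tool, the strand setting and any read filter are not given in the sources used here. Reads from overlapping genes on opposite strands therefore cannot be assigned with certainty, and reads of near-identical genes, such as those of the major urinary proteins, could be split. Every one of the 27277 rows has at least 1 count, and 23 gene names look like dates. The same deposited table carries the authors' own comparison as a fold change (ratio), a log2 fold change, a p-value and an adjusted p-value, and marks genes as significant. The largest marked adjusted p is 0.0497 and the smallest marked absolute log2 fold change is 1.00. The submitters' processing notes for the RNA samples name no tool for that comparison. For tested genes its log2 fold changes had a correlation of 0.9992, across genes, with those computed here. The ChIP lists are in the narrowPeak layout, 1 per library, and BWA, SAMtools, MACS2, deepTools and DESeq2 are named without versions in the submitters' processing notes for the ChIP samples. Each row gives a score, a fold over background (ratio), a -log10 p-value and a -log10 q-value as deposited by the authors, and the lowest -log10 q is 1.31 in the control and 1.3 in the knockout list. Whether an input library was used for calling is not given in the sources used here. Peaks were called per library, since each list belongs to 1 sample. The fold is the peak's own value in its list and was used to rank, filter or describe within it, except that the closing part derives read numbers and backgrounds from fold and p-value and sets those of both lists side by side.

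For the RNA counts, genes were filtered with filterByExpr (minimum count 10, total 15), which left 15135 genes. Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust, two-sided, genotype as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.235. CPM values use the TMM-scaled library sizes. The TMM factors were 0.816 ± 0.0374 in the controls and 1.23 ± 0.0377 in the knockouts (SD, n = 3). On simulated counts for the 15135 genes of this comparison, 36% of 100 genes changed 2-fold and 86% of 100 genes changed 4-fold were recovered, with 14 false calls among 14935 unchanged genes. No other genes were changed in the simulation, whereas 3865 were called in the data. The adjustment depends on the share of changed genes, so these rates do not give the recovery in the data.

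A total of 28 gene lists were fixed before the data were examined, with 824 entries, of which 817 were in the table. They cover gluconeogenesis, the glucagon response, glycolysis, lipid and bile acid metabolism, amino acid breakdown, plasma proteins, transcription factors, drug metabolism, stress and immune responses, cell cycle, p53, culture, fetal liver, Mediator, RNA polymerases, mitochondrial mRNAs and markers of other cell types. Of the entries not matched, the genes were not analysed here. Each list was tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists. Of the 28 lists, 15 passed with the preset, 0 with an estimated correlation (smallest adjusted p 0.122) and 9 with fry, which asks whether a set moves on balance in one direction without comparing it with other genes. The direction of fry differed from that of camera for the RNA polymerase list. Med19 was left out of the Mediator list and of counts of changed members.

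The genes named in the text were set by a rule fixed before the data were examined. It takes Med19, G6pc, Pck1, Fbp1, Pcx, Slc37a4 and Ppargc1a, the 6 largest rises and the 6 largest falls among genes past the threshold with at least 5 CPM in the higher group and no overlap of the groups, and the 2 members of each list with the smallest adjusted p, or the most abundant member where none passed. Other members of lists are named where 5 or fewer rose or fell, after their values were seen. For the peaks it takes the region nearest the starts of G6pc, Pck1 and Med19, and the 5 protein-coding genes with the highest fold at a start summit. Some genes that these rules take are not reported here by name, though counts include them.

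Rows of a peak list with the same start and end are summits of 1 region and were counted as 1 region. Overlaps of at least 1 bp were found with bedtools 2.31.1. Gene starts were the 5′ ends of the genes in the RNA table, which shares mm10 with the lists, and tRNA genes came from RefSeq genes of GRCm38.p6, the same build. Random positions were drawn 20 times on the same chromosomes. Intervals are 95% exact binomial ones (Clopper-Pearson) from SciPy 1.17.1, and these, like the ratios of single genes, cover counting error only. The sequencing depth of the ChIP libraries is not given in the sources used here. Permutation tests used 100000 resamples, or 10000 for the comparison of genes that kept or lost a knockout summit, in Python 3.11.15 with numpy 2.4.6, and were checked on simulated values.

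Alternatives fixed before the data were examined were RLE and upper-quartile factors and library size alone, the Wald test of DESeq2 1.42.0, limma-voom, no count filter and a filter of 50 counts in 3 libraries, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and stricter peak thresholds, overlaps and start distances. Those added after seeing the data left out the mitochondrial rows, looked again at the fit without control replicate 1, counted each summit, and limited the control list to the lowest -log10 p of the knockout list.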

Results

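The libraries came from mouse primary hepatocytes, the main metabolic cells of the liver, kept in culture for 24 h and stimulated with 100 nM glucagon, the fasting hormone that drives hepatic glucose output, for 12 h. Control cells carried the floxed Lcmr1 gene and knockout cells lacked it in hepatocytes. Lcmr1 is an older name of Med19, a subunit of Mediator, the complex that links DNA-bound transcription factors to RNA polymerase II. RNA was sequenced in 3 control and 3 knockout libraries, and chromatin immunoprecipitation (ChIP) was sequenced in 1 library per genotype. Every library received glucagon, so the response to the hormone itself cannot be read from these data. Total gene counts per RNA library ranged from 22191786 to 26595249. The series title asks whether Lcmr1 is required for transcription of G6pc, the catalytic subunit of glucose-6-phosphatase, and for glucose production.

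Med19 (ENSMUSG00000027080, chromosome 2, 84678402 to 84688215, mm10, plus strand) was lower in the knockout libraries. Its counts were 154, 226 and 248 in the controls and 90, 166 and 97 in the knockouts, or 10.5 ± 2.94 and 3.73 ± 1.33 CPM (counts scaled to the TMM-adjusted library size, SD, n = 3). The log2 fold change was -1.50 (SE 0.31, adjusted p = 0.012 in the edgeR quasi-likelihood test). The counts cover the whole gene, so they do not show the deleted exons alone, and part of the gene overlaps Tmx2 and Zdhhc5 on the opposite strand. Without knockout replicate 1, edgeR gave -1.35 with an adjusted p of 0.0505.

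G6pc (ENSMUSG00000078650, chromosome 11, 101367561 to 101377903, plus strand) did not pass the test in these cells. It stood at 447 ± 27.2 CPM in the controls and 401 ± 89.4 CPM in the knockouts (SD, n = 3), and the values of the groups overlapped. Its log2 fold change was -0.16 (SE 0.17, edgeR adjusted p = 0.5325). Scaled by library size alone, the sign turned, with a log2 fold change of 0.43 (edgeR adjusted p = 0.0717). The authors' deposited table gives G6pc a log2 fold change of -0.17 and an adjusted p of 0.6155, and does not mark it as significant.

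Pck1, the cytosolic enzyme that makes phosphoenolpyruvate from oxaloacetate, fell from 4519 ± 223 to 1837 ± 374 CPM (SD, n = 3, log2 fold change -1.298, SE 0.16, edgeR adjusted p = 0.001671). Pyruvate carboxylase, Pcx, fell by 0.39 on the log2 scale (edgeR adjusted p = 0.04223), a change that turned to 0.21 when scaled by library size alone (edgeR adjusted p = 0.133). That call also ended in each fit that left out a library other than control replicate 1, with edgeR adjusted p from 0.0711 to 0.122, and with upper-quartile factors or no count filter. The other genes of glucose output named beforehand did not pass the edgeR test. Fructose-1,6-bisphosphatase, Fbp1, had a log2 fold change of -0.28 (edgeR adjusted p = 0.1068), which became 0.32 (edgeR adjusted p = 0.0391) under library size alone. The glucose-6-phosphate transporter Slc37a4 had 0.28 (edgeR adjusted p = 0.09026) and the coactivator Ppargc1a had 0.37 (edgeR adjusted p = 0.2902). Both passed under library size alone, at 0.87 and 0.97, Slc37a4 also with upper-quartile factors, at 0.35, and Ppargc1a also passed without control replicate 1, at 0.67.

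Over the list of 24 gluconeogenic enzymes and transporters, 4 members rose and 5 fell over all genes tested, and 5 rose and 7 fell when adjusted over the list alone. Under library size alone, 14 rose and 3 fell. The members that fell were Pck1, Pcx, the glycerol channel Aqp9 (-1.32), the mitochondrial carrier Slc25a10 and glycerol kinase, Gk. Those that rose were malate dehydrogenase Mdh2 (1.34), the mitochondrial enzyme Pck2, Ldhb and Slc25a11. The list as a whole did not stand apart from other genes (camera adjusted p = 0.861), and its median of -0.06 and its mean of 0.03 differed in sign; the median turned to 0.53 under library size alone and to 0.04 without control replicate 1. In the list of 34 genes of the glucagon and cyclic AMP response, 1 rose (Per1) and 6 fell, both over all genes tested and adjusted over the list alone. Without control replicate 1 these numbers were 6 and 9, and under library size alone 15 and 1. The glucagon receptor Gcgr fell from 452 ± 36.2 to 243 ± 16.1 CPM (SD, n = 3, edgeR adjusted p = 0.001992), a call that ended under library size alone (edgeR adjusted p = 0.0699). Hnf4a, a master regulator of hepatocyte genes, fell from 1492 ± 262 to 583 ± 99.1 CPM (edgeR adjusted p = 0.002242). This list had a camera adjusted p of 0.47, and its median of -0.05 turned to 0.54 under library size alone and to 0.11 without control replicate 1.

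**Figure D1:**
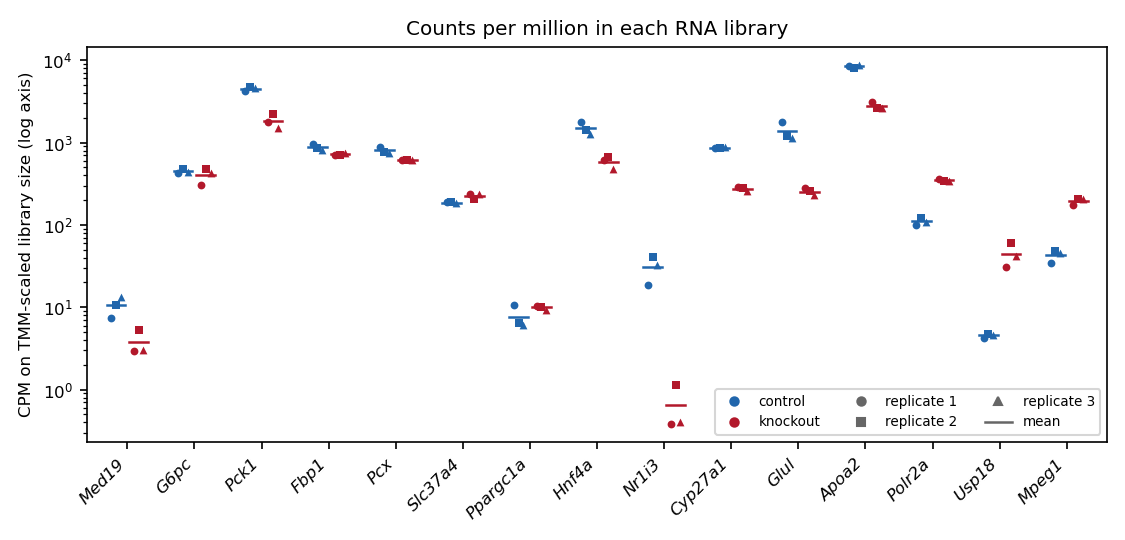
CPM, on a log axis, of 15 genes in each of the 3 control (blue) and 3 knockout (red) libraries, where marker shapes are replicates and bars are means. G6pc points overlap between the groups (means 447 and 401), whereas Pck1 points do not (means 4519 and 1837).

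Across the transcriptome, 3865 of 15135 genes tested changed in the knockout at an edgeR adjusted p under 0.05, with 1905 higher and 1960 lower. Of these, 1145 rose and 794 fell by at least 2-fold, and 5990 genes had an unadjusted p under 0.05. The balance of the directions rests on the scaling. The 10 most abundant genes took 18.4 ± 0.405% of the counts in the controls and 12 ± 0.162% in the knockouts (SD, n = 3), and the albumin gene, Alb, took 6.12 ± 0.33% and 1.99 ± 0.468%. Without the TMM factors, edgeR called 7711 genes higher and 617 lower, and the median log2 fold change of all genes moved up by 0.588. The factors are set over the bulk of genes, so this shift does not come from the 10 most abundant genes alone. Changes are therefore given relative to the bulk of genes, as the TMM factors set it. The number of calls also rests on single libraries, with 2419 and 2360 genes without control replicates 2 and 3 and 2236 and 2570 without knockout replicates 1 and 2.

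The largest rises among genes with at least 5 CPM were in genes close to silent in the controls. Lrtm2 went from 0.07 ± 0.083 to 27.3 ± 12.5 CPM, A1bg, a plasma glycoprotein gene, from 0.083 ± 0.101 to 19.4 ± 6.73, Myo7b from 0.153 ± 0.138 to 21.3 ± 6.36 and Pkp1 from 0.082 ± 0.025 to 8.68 ± 3.47 (SD, n = 3). Col22a1 had 1 count in all controls together and 557 in the knockouts, a ratio of 354 (95% exact counting interval 63.2 to 14000), and Wfdc16 had 3 and 662, a ratio of 140 (47.8 to 681). At the other end, Obp2a had 502 counts in the controls and 1 in the knockouts, a ratio of 790 (141 to 31300). The steroid enzyme gene Hsd3b5 fell from 153 ± 122 to 0.36 ± 0.624 CPM, the fatty acid elongase gene Elovl3 from 695 ± 42.5 to 8.72 ± 10.5, and Pitx3, which lies beside Elovl3 on chromosome 19, from 24.3 ± 3.29 to 0.297 ± 0.433 (SD, n = 3). Pitx3 lies on the minus strand and ends at 46135685, shortly past the end of Elovl3 on the plus strand at 46135307. The strand setting is not given, so reads running past Elovl3 could be part of the Pitx3 counts. The major urinary protein genes Mup17 and Mup11 fell, with log2 fold changes of -7.35 and -6.76, but these genes are near-identical copies and the counting could have split their reads. All 12 genes passed the edgeR test, which the rule that chose them requires. The calls of Hsd3b5, Elovl3 and Mup17 ended under several alternatives. Their edgeR adjusted p were 0.0655, 0.0703 and 0.0838 without knockout replicate 1 and 0.0546, 0.0528 and 0.0668 without control replicate 3. Single libraries also moved the sizes. Without knockout replicate 2 the log2 fold changes of Elovl3, Pitx3, Mup17 and Mup11 were -7.98, -8.86, -9.11 and -8.23, in place of -6.32, -6.33, -7.35 and -6.76, and the remaining knockout libraries had 0 counts of Hsd3b5 and Obp2a. The fitted rises rest on few control counts, and went from 8.57 to 7.98 and 9.89 for Lrtm2 without control replicates 2 and 3, from 7.79 to 9.34 and 7.19 for A1bg without control replicates 1 and 2, and from 7.10 to 6.52 and 7.72 for Myo7b without control replicates 1 and 3.

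Most tested genes of drug metabolism, bile acid metabolism and the plasma proteins fell. In the drug metabolism list, 29 of 42 members fell and 2 rose (29 and 3 adjusted over the list alone), with a median log2 fold change of -1.17. Gsta3 fell from 1944 ± 239 to 523 ± 28.4 CPM and Cyp1a2 from 698 ± 129 to 157 ± 17.4 (SD, n = 3). Fmo1 and Cyp2b10 were the members that rose. In the bile acid list, 14 of 23 members fell and 2 rose, Klb and Akr1d1 (17 and 2 adjusted over the list alone, median -1.28). Cyp27a1, an enzyme of bile acid synthesis, fell from 862 ± 11 to 275 ± 13.7 CPM and the sterol carrier gene Scp2 from 4187 ± 184 to 1134 ± 220 (SD, n = 3). Of 51 plasma protein genes, 36 fell and 3 rose (39 and 3 adjusted over the list alone, median -0.92), with Apoa2 down from 8427 ± 424 to 2771 ± 269 CPM (SD, n = 3). The risers were A1bg, Pros1 and F12. The 3 lists had camera adjusted p of 5.12e-17, 4.5e-11 and 4.5e-11, and adjusted p of 0.329, 0.329 and 0.122 with an estimated correlation. In the same libraries, markers of macrophages, stellate cells and endothelial cells had medians of 0.83, 0.46 and 0.43. With library size alone, 24, 12 and 21 members of the 3 lists fell and 6, 4 and 8 rose, and without control replicate 1 drug metabolism had 29 that fell and 4 that rose.

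Among 37 genes of the urea cycle and amino acid breakdown, 15 fell and 1 rose, Bckdha (18 and 3 adjusted over the list alone). Glutamine synthetase, Glul, fell from 1373 ± 346 to 254 ± 23.9 CPM and histidine ammonia-lyase, Hal, from 619 ± 112 to 196 ± 27.4 (SD, n = 3). In the list of 38 hepatocyte transcription factors, 14 fell and 3 rose, Esr1 and Esrra among them (14 and 4 adjusted over the list alone). The xenobiotic receptor gene Nr1i3, which overlaps Tomm40l on the other strand, fell from 30.9 ± 11.3 to 0.645 ± 0.432 CPM (log2 fold change -5.57, and -6.28 without knockout replicate 2), and the aryl hydrocarbon receptor gene, Ahr, from 31.1 ± 1.33 to 14.1 ± 0.697 (SD, n = 3). Of 25 antioxidant targets of Nrf2, 11 fell and 3 rose, Abcc4, Pgd and Cbr3 (12 and 4 adjusted over the list alone), with Gstm3 down from 69.4 ± 6.40 to 28.2 ± 3.75 CPM and Ugdh from 249 ± 23.9 to 113 ± 7.58 (SD, n = 3). Of 32 genes of fatty acid oxidation and ketogenesis, 9 fell and 2 rose, Cd36 and Hadhb (10 and 2 adjusted over the list alone). Acsl1, which activates fatty acids, had a log2 fold change of -1.48, while Cd36, which takes them up, rose by 1.66. These 4 lists had camera adjusted p of 0.000276, 0.0184, 0.0065 and 0.0264, and adjusted p of 0.329, 0.524, 0.329 and 0.73 with an estimated correlation. Under library size alone their medians lay above 0, at 0.09, 0.39, 0.04 and 0.32, still below the median of all genes at 0.60, and the macrophage markers had a median of 0.83 in the TMM-scaled fit. When scaled by library size alone, 7, 7, 7 and 6 members fell and 12, 13, 7 and 10 rose, and without control replicate 1 the amino acid list had 19 that fell and 4 that rose. The transcription factor call ended without knockout replicate 3 (camera adjusted p of 0.0856).

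**Figure D2:**
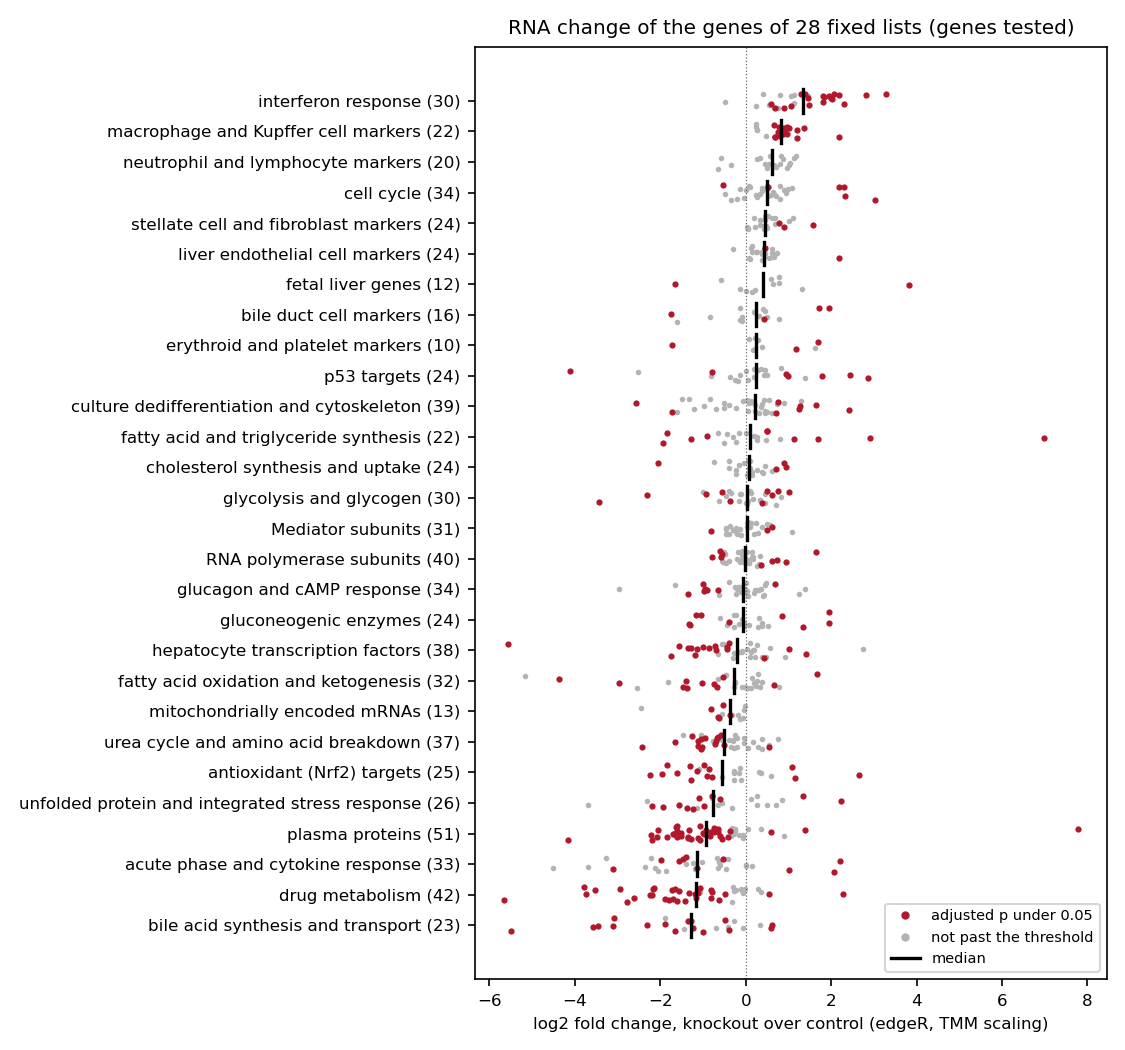
Log2 fold change of knockout over control for each gene of the 28 lists, ordered by their medians (black bars), with red points for genes past an adjusted p of 0.05 and the number of genes tested in parentheses. The bile acid list has the lowest median (-1.28) and the interferon list the highest (1.33).

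More genes of protein folding and the acute phase fell than rose, in libraries whose macrophage markers had a median of 0.83. Of 26 genes of the unfolded protein and integrated stress responses, 9 fell and 2 rose, Ddit4 and Sesn2 (12 and 2 adjusted over the list alone). Herpud1, of the degradation machinery of the endoplasmic reticulum, fell from 1469 ± 77.2 to 385 ± 102 CPM, and Ddit4, an inhibitor of mTOR signalling, rose from 11.7 ± 2.56 to 55.3 ± 11.4 (SD, n = 3). Of 33 genes of the acute phase and cytokine response, 7 fell and 3 rose, Vcam1, Cxcl2 and Il33 (9 and 3 adjusted over the list alone). Ceruloplasmin, Cp, had a log2 fold change of -1.46 and Vcam1 of 2.06. All 13 mitochondrially encoded mRNAs lay below 0 and 5 fell, mt-Cytb (-0.81), mt-Nd4 (-0.64), mt-Nd2, mt-Atp6 and mt-Co1 (5 adjusted over the list alone). Their median turned from -0.37 to 0.22 under library size alone, where the calls of mt-Cytb and mt-Nd4 ended, and the share of all counts from the mitochondrial genome was 5.85 ± 0.0786% in the controls and 6.6 ± 0.316% in the knockouts. The 3 lists had camera adjusted p of 0.0264, 0.0184 and 0.0421, and adjusted p of 0.698, 0.732 and 0.698 with an estimated correlation. Without control replicate 1 these calls ended (camera adjusted p of 0.0931, 0.163 and 0.0931), as did that of fatty acid oxidation (0.127). Those of protein folding, mitochondrial mRNAs and fatty acid oxidation also ended without knockout replicate 3 (0.204, 0.0941 and 0.154). Without control replicate 1, 13 acute phase genes fell and 5 rose, and their median moved from -1.14 to -0.26. With library size alone, 4 genes of protein folding fell and 6 rose, 4 acute phase genes fell and 3 rose, and 4 mitochondrial mRNAs rose.

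Other metabolic lists split between rises and falls and had no camera call. Of 22 genes of fatty acid and triglyceride synthesis, 6 rose and 4 fell (7 and 4 adjusted over the list alone). The elongase Elovl6 rose from 31.3 ± 2.27 to 100 ± 11.5 CPM, and the desaturase Scd1 fell from 3364 ± 891 to 880 ± 94.6 (SD, n = 3). The others that fell were Elovl5, Me1 and Agpat2. Of 24 genes of cholesterol synthesis and uptake, 3 rose, Dhcr7 (0.95) and Mvk (0.90) among them, and 1 fell, Fdps (-2.06), over all genes tested and adjusted over the list alone. Of 30 genes of glycolysis and glycogen, 5 rose and 5 fell (6 and 5 adjusted over the list alone). Pgam1, Gpi1, Pgm1, Pfkl and Pkm rose, Pgam1 by 0.62, and the members that fell included the glucose transporter Slc2a2, Pfkfb1, Pgm2 and Gapdh. Pgm2 fell by 0.56 and had a log2 fold change of 0.03 under library size alone. The camera adjusted p of these lists were 0.861, 0.861 and 0.864. With library size alone, 11, 11 and 15 members rose and 3, 1 and 2 fell, and without control replicate 1 these numbers were 6, 5 and 7 and 6, 2 and 9. For glycolysis the median was 0.03, the mean -0.13 and the camera direction down.

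Interferon response genes were higher in the knockout. Of 30 members, 19 rose and none fell (24 and 0 adjusted over the list alone), with a median log2 fold change of 1.33. Usp18, which restrains interferon signalling, rose from 4.55 ± 0.23 to 44.1 ± 14.8 CPM, and the regulator Irf7, which overlaps Phrf1 on the other strand, from 37.7 ± 12.5 to 131 ± 18.6 (SD, n = 3). The camera adjusted p was 4.19e-10, with an adjusted p of 0.524 with an estimated correlation. Macrophage markers had a median of 0.83 in the same libraries. When scaled by library size alone, 29 members rose.

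Markers of macrophages, including the Kupffer cells of the liver, rose as well. Of 22 markers, 16 rose and none fell (17 and 0 adjusted over the list alone), and the median was 0.83. Mpeg1 rose from 43 ± 7.53 to 195 ± 19.1 CPM and Cd5l from 67.6 ± 9.04 to 132 ± 5.89 (SD, n = 3). The camera adjusted p was 3.57e-08, with an adjusted p of 0.494 with an estimated correlation. Of 24 stellate cell and fibroblast markers, Mgp (1.57), Postn (0.78) and Col1a2 rose and none fell, and no marker passed when adjusted over the list alone. Of 24 liver endothelial markers, Lyve1 (2.18) and Robo4 (0.44) rose and none fell (1 and 0 adjusted over the list alone). These 2 lists had medians of 0.46 and 0.43, camera adjusted p of 0.0139 and 0.0205, and adjusted p of 0.698 and 0.732 with an estimated correlation, and both calls ended without control replicate 1 (camera adjusted p of 0.1 and 0.0691). The calls of Mgp, Postn and Robo4 ended without knockout replicate 1 (edgeR adjusted p of 0.0732, 0.128 and 0.128) and under several other alternatives. Of 16 bile duct markers, 3 rose, Bicc1 (1.72) and Prom1 among them, and 1 fell, Onecut1 (-1.75), over all genes tested and adjusted over the list alone. Of 10 erythroid and platelet markers, Itga2b (1.18) and Ppbp rose and Alas2 (-1.72) fell, likewise under both adjustments, though the Alas2 call ended with no count filter (edgeR adjusted p of 0.0782). No neutrophil or lymphocyte marker passed edgeR among 20 tested, over all genes tested or adjusted over the list alone, with 2 at an unadjusted p under 0.05, and the most abundant, Ighm, ranged widely within both groups (12.6 ± 9.19 and 15.7 ± 15.4 CPM, SD, n = 3). These 3 lists had camera adjusted p of 0.633, 0.471 and 0.137. With library size alone, 20 macrophage, 16 stellate, 23 endothelial, 5 bile duct, 5 erythroid and platelet and 11 neutrophil and lymphocyte markers rose, and 1 of the last rose without control replicate 1.

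Of 34 cell cycle genes, 5 rose, E2f2 (3.04), Mybl2 (2.31), Ccna2, Ccne1 and Aurka, and Mcm7 fell (4 and 1 adjusted over the list alone). The camera adjusted p was 0.0238, with an adjusted p of 0.698 with an estimated correlation, and the call ended without control replicate 1 (camera adjusted p of 0.15), without knockout replicate 3 (0.0856) and under library size alone (0.397). Markers of macrophages, stellate cells and endothelial cells had medians of 0.83, 0.46 and 0.43 in these libraries. Of 24 targets of p53, 5 rose, Gtse1 (2.85, and 3.55 without control replicate 1), Rrm2b, Psrc1, Plk2 and Phlda3, while Ephx1 and Perp fell (6 and 2 adjusted over the list alone). Perp, a membrane protein of epithelial junctions, went from 95.4 ± 9.44 to 5.53 ± 2.2 CPM (SD, n = 3). Of 39 genes of culture dedifferentiation and the cytoskeleton, 6 rose and 2 fell, S100a10 and Tubb2a (9 and 3 adjusted over the list alone), with the annexins Anxa5 and Anxa2 up by 1.28 and 1.63. Of 12 fetal liver genes, Igdcc4 (3.83, and 2.76 without knockout replicate 3) rose and Peg3 (-1.65) fell, under both adjustments, and the Peg3 call ended without any one of the knockout replicates (edgeR adjusted p from 0.0594 to 0.0843). The last 3 lists had camera adjusted p of 0.486, 0.307 and 0.476. Without control replicate 1 they had 9, 10 and 3 members that rose and 3, 5 and 1 that fell. With library size alone, 15 cell cycle genes rose, and in the other lists 13, 20 and 6 rose and 1, 2 and 1 fell.

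Transcripts of the transcription machinery mostly did not pass the test, with some exceptions. Of the 31 other Mediator subunits tested, Med28 (0.63) and Med13 (0.49) rose and Med11 fell (2 and 0 adjusted over the list alone), and the calls of Med28 and Med13 ended without control replicate 2 (edgeR adjusted p of 0.0526 and 0.0661), control replicate 3 (0.053 and 0.0797) or knockout replicate 1 (0.0571 and 0.0814). The camera adjusted p was 0.861, and the median of 0.02 and mean of -0.001 differed in sign. Of 40 RNA polymerase subunits and polymerase III factors, 5 rose and 4 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.967). Polr2a, the largest subunit of RNA polymerase II, rose from 111 ± 11.3 to 348 ± 13.5 CPM and Polr3gl from 10.2 ± 1.56 to 19.7 ± 2.68 (SD, n = 3). Polr2l, Polr2d and Gtf3c4 also rose, and Gtf3c6, Polr2i, Polr3a and Polr3g fell. When scaled by library size alone, 18 Mediator and 26 RNA polymerase genes rose, and without control replicate 1 the Mediator list had 2 that rose and 2 that fell.

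Control replicate 1 stood apart from the other controls. It was separated from them on the second principal component, which held 19.4% of the variance, while the first (64.8%) separated the genotypes. Genes chosen after their values were seen show the gap. The metal-binding protein gene Mt1 stood at 946 CPM in this library and at 8.58 and 7.92 in the other controls, the early response gene Egr1 at 1563 against 45.3 and 43.8, and Hsd3b5 at 11.9 against 217 and 230. Without this library edgeR called 4921 genes (2407 higher and 2514 lower), with 3559 of the 3865 calls kept in direction, and 8 of the 15 lists with a camera call. The authors' deposited table marks 2229 genes as significant (1281 up and 948 down), each with an absolute log2 fold change of at least 1, and 1892 of them passed edgeR here.

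The ChIP lists describe where the precipitated protein was found. The sample titles name RNA polymerase III as the target, whereas the series design names Lcmr1, so the target is not settled by the labels. The control list held 22793 summits in 16995 distinct regions covering 10.4 Mb, and the knockout list 1649 summits in 1309 regions covering 0.669 Mb. With 1 library per genotype there was no replicate check, and no test between genotypes was made. Of the knockout regions, 1122 (85.7%, 95% exact binomial interval 83.7 to 87.6) overlapped a control region, whereas 761 of the control regions (4.48%, 4.17 to 4.8) overlapped a knockout region. These shares depend on the list lengths, and a reciprocal overlap of 50% was met by 17.6% of the knockout and 1.36% of the control regions.

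Control regions lay at and within genes. A summit lay within 1000 bp of a gene start in 27% of control regions (26.4 to 27.7) and 22.8% of knockout regions (20.5 to 25.1), against 1.97% and 2.45% of random positions. Protein-coding genes held 82.5% of the bases covered in the control list and 78.8% in the knockout list. Of 13033 protein-coding genes tested, 5828 had a control region within 500 bp of the gene and 620 a knockout region. For the gluconeogenic list these numbers were 22 and 10 of 24, for drug metabolism 32 and 6 of 42, for interferon response 8 and 1 of 30, and for macrophage markers 2 and 0 of 22. Of 408 nuclear tRNA genes, which RNA polymerase III transcribes, 6 (1.47%, 0.541 to 3.17) had a control region within 100 bp and 0 a knockout region (0 to 0.9%). Of 7 other genes of RNA polymerase III, 1 had a control region. A control summit lay within 1000 bp of the start in 4346 of the 13033 protein-coding genes (33.3%). These values argue against RNA polymerase III as the precipitated protein, unless reads of the repeated tRNA genes were lost in mapping, which is not known. The windows for tRNA and protein-coding genes differ, and the values do not show whether Lcmr1 was precipitated instead. By the authors' fold, the strongest start summits of protein-coding genes included those at Jund (32.8), Necab2 (28) and Tob1 (27.2) in the control list. In the knockout list they included those at Actb (18.6), Hist1h4c (14.7) and H2-Q10 (12.7).

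G6pc was covered from end to end by a single control region of 12056 bp (chromosome 11, 101367529 to 101379584, mm10) with 22 summits. In the knockout list, 6 separate regions lay over the gene or within 500 bp of it, covering 5263 bp, and the nearest to the start began 2739 bp downstream of it (101370300 to 101370852). A further knockout region past this margin (101378869 to 101379216) also lay within the span of the control region. Pck1 had 1 region in each list, of 8620 bp in the control (chromosome 2, 173152971 to 173161590) and 7731 bp in the knockout (173153294 to 173161024), and the knockout region began 246 bp downstream of the gene start. The highest fold of the authors within these control regions was 39 at G6pc and 55.5 at Pck1, in a list whose highest is 72.8. No region of either list lay over Med19, and the nearest control region was 27579 bp from its start (84650485 to 84650823).

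**Figure D3:**
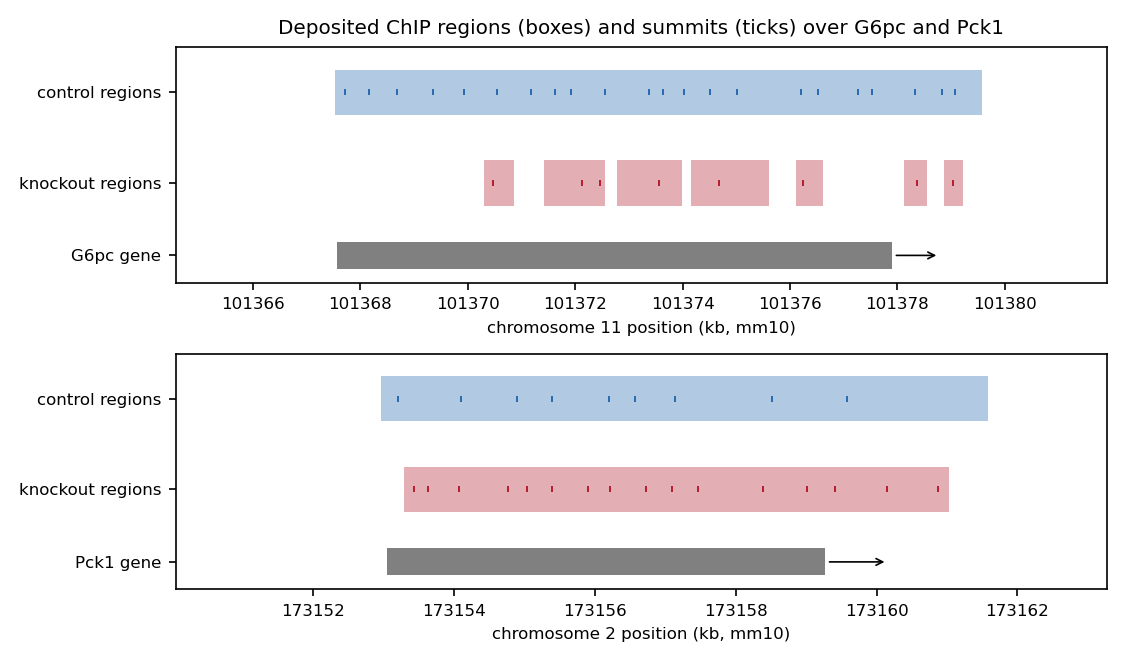
Deposited ChIP regions (boxes) and summits (ticks) of the control and knockout libraries over G6pc on chromosome 11 and Pck1 on chromosome 2, with positions in kb (mm10) and the genes in grey, where arrows give the direction of transcription. At G6pc the control region spans 12056 bp, whereas the knockout regions over the gene or within 500 bp of it cover 5263 bp. The control length runs past that margin, and so does a further knockout region (101378869 to 101379216) that is not counted.

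Genes with a control summit at their start were lower in the knockout RNA than other genes. The median log2 fold change was -0.10 over 4751 tested genes with a summit within 1000 bp of the start and 0.08 over 10384 genes without, a difference of -0.175. Permuting the summit status within 20 bins of mean expression gave a mean difference of -0.115 and a two-sided p of 1e-05, the smallest that 100000 resamples can give. Of the genes with a summit, 17.3% were lower and 9.37% higher in the knockout at an edgeR adjusted p under 0.05, against 10.9% and 14.1% of the genes without. These values are across genes, which are not independent replicates, and most of the difference in medians is also present in the permuted data, since abundant genes have more summits. Summit status came from the control library alone and the bins from the mean of both genotypes. Within a bin, genes more active in control cells could therefore have both a summit and a lower log2 fold change. Control regions also lay within 500 bp of 34 of 37 genes of amino acid breakdown, but of 8 of 30 interferon genes and 2 of 22 macrophage markers. The difference may thus restate in part which lists fell and which rose.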

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

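Leaving out the mitochondrial rows, the second look at the fit without control replicate 1, counting each summit and matching the lowest -log10 p were chosen after seeing the data. For 73 named genes over 15 settings, 1019 values kept their direction and side of the threshold, 62 lost the call, 4 gained it and 6 turned. For the lists these numbers were 352, 21, 1 and 17. Of the other values 57 stayed close and 45 moved, where a count is close within 1.5 times, a percent within the 95% exact interval of the reported value, and the RNA difference by start summit if its direction and call stay. A list counts as turned where its camera direction did. The alternatives for a table without counts were not run, since the table holds counts, and DESeq2 gave no list test. The cause was not tested, except that left-out libraries and stricter thresholds leave fewer samples or fewer calls.

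At an adjusted p under 0.01 edgeR called 1655 genes (798 higher, 857 lower), and with an absolute log2 fold change of at least 1 it called 1939 (1145 and 794). Library size alone gave 8328 (7711 and 617), with G6pc at 0.43, Fbp1 at 0.318, Pcx at 0.208, Pgm2 at 0.026 and, for lists whose camera direction turned, medians of 0.528 (gluconeogenic), 0.69 (cholesterol), 0.982 (fetal liver), 0.626 (Mediator), 0.565 (RNA polymerase) and 0.841 (bile duct). The RNA polymerase median was 0.047 with upper-quartile factors and 0.003 with the stricter filter, and that of glycolysis 0.078 with limma-voom. Of the 28 lists, 0 passed camera with an estimated correlation (15 with the preset, 9 with fry).

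Without single libraries edgeR called from 2236 (without knockout replicate 1) to 4921 genes (without control replicate 1), 1119 to 2407 higher and 1104 to 2514 lower, and at the fewest 8 lists passed camera. Med19 ranged from -1.841 to -1.297 and lost its call, at -1.353, without knockout replicate 1. Ighm ranged from -0.851 to 0.778 and lay at -0.189 without control replicate 1. List medians ranged from -0.17 to 0.041 (gluconeogenic), -0.147 to 0.106 (glucagon), 0.002 to 0.159 (fatty acid synthesis), -0.142 to 0.09 (Mediator) and -0.067 to 0.048 (RNA polymerase), where the camera direction turned without control replicate 1, and from -0.06 to 0.436 (cholesterol), where it turned without control replicates 2 and 3 (-0.011) and knockout replicate 2 (-0.039).

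The numbers do not pair the samples, as the correlations of deviations were 0.11, 0.052 and 0.094, although all 6 libraries correlated best with their own number, a hint from the data and not the design. With the replicate block edgeR called 3468 genes (1713 higher, 1755 lower) and 14 lists passed camera. Pcx (edgeR adjusted p of 0.0796), Mup17 (0.0517), Robo4 (0.0573), Postn (0.0761) and the mitochondrial mRNAs (camera adjusted p of 0.0707) did not pass.

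Regions with a -log10 q of at least 5 numbered 6432 in the control and 480 in the knockout list, and those with a fold of at least 5 numbered 8362 in the control. The shared percent of control regions was 5.76 (fold), 5.14 (control at the lowest -log10 p of the knockout list), 1.48 and 1.36 (overlap of 50%, one-way and reciprocal) and 14.3 (each summit), and of knockout regions 83.2 (fold), 81.1 and 17.6 (overlaps) and 88.2 (each summit). The percent at gene starts was 44.4 (-log10 q), 38.2 (fold), 29.6 (lowest -log10 p), 24.1 and 34.4 (500 and 3000 bp) and 22.3 (each summit) for the control, and 26.2 (-log10 q), 17.8 and 35.4 (500 and 3000 bp) and 19.8 (each summit) for the knockout. Of simulated 2-fold changes in RNA, 36% were recovered, in a simulation with far fewer changed genes than were called in the data. How much of this comes from depth was not tested.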

Other observations

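All tests in this part, those on sex-biased genes, macrophages, ChIP regions and other splits of the libraries, were written down after the results were seen.

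Genes that differ between male and female mouse liver moved apart in the knockout. In a list of 19 male-biased genes written from general knowledge after many values had been seen, 14 fell and none rose, with a median log2 fold change of -2.47. In a list of 25 tested female-biased genes, written in the same way, 16 rose and 1 fell (Tox). The median was 2.53, also with the 4 genes of at most 3 counts in a group set to a floor of 3 counts over the group. The lists hold genes already named above for their large change, such as Hsd3b5, Elovl3 and A1bg, so these counts and medians rest in part on that choice. Some female-biased genes that rose stayed near the floor, such as Cyp3a41a and Cyp3a41b at 0.709 and 0.487 CPM in the knockouts. Among the male-biased genes, the transporter Slco1a1 fell from 286 to 6.29 CPM, Cyp4a12a from 324 to 30.7 and Mup20 from 2206 to 81.4. Among the female-biased genes, Cyp2a4, a near-identical copy of Cyp2a5, rose from 1.02 to 87.1 CPM, the receptor gene Ntrk2 from 2.25 to 66.9 and Cux2 from 1.64 to 14.1. Without control replicate 1, in which Hsd3b5 is low, 7 male-biased genes fell and 20 female-biased genes rose and 2 fell in edgeR.

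The sex-biased pattern was weighed against 3 explanations. Female animals among the knockouts are argued against by Xist, with at most 6 counts in a knockout library, beside at least 336 counts of each of 4 Y-linked genes. A general loss of hepatocyte transcripts would by itself raise none of the female-biased genes, of which 16 rose in edgeR. That count restates the rise itself, so it is no independent test of this explanation. The explanation stays open for the fall of the male-biased genes. Lower growth hormone signalling may be involved, since this hormone sets many sex-biased genes, but of its targets Igf1, Socs2 and Cish, all below 0, 1 passed edgeR (Igf1, at -1.62), and Igf1 is also in the plasma protein list that fell, so this stays open. An effect of the knockout itself and the age, litter or housing of the animals, which the labels do not give, were not told apart by any test here.

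The rise of interferon genes and macrophage markers was weighed against cell composition. A lower share of hepatocytes as the whole cause would lift the markers of all other cells alike. Macrophage markers lay 0.396 above the 64 markers of endothelial, stellate and bile duct cells (permutation p = 6e-05). Those 64 had a median of 0.434. Above 0 were 24 of 24 stellate, 23 of 24 endothelial and 9 of 16 bile duct markers. The permutation shuffles genes, which move together (estimated correlation 0.402 in the macrophage list), so its p-value does not measure the spread between libraries. A lower share of hepatocytes therefore stays open, at least as part of the rise. More macrophage RNA may account for the marker rise but was not tested independently of it, since the share of markers above 0 (100%) restates the rise. The 3 most abundant in the controls were Clec4f (73.8 to 148 CPM), Cd5l (67.6 to 132) and C1qa (52.5 to 84.4), and 0 of the markers are held by another list. As the whole cause of the interferon rise, more macrophage RNA would put the interferon median no higher than that of the macrophage markers. The interferon median lay 0.503 above it (permutation p = 0.0071). This permutation too shuffles genes that move together (estimated correlation 0.542 in the interferon list), so it leaves this explanation undecided. Whether more macrophages were present or each held more of these transcripts stays open, as does an interferon response of the hepatocytes themselves.

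The short knockout peak list was weighed against depth and yield. The fold and p-value of each summit imply a whole number of reads and a background, recovered for 100% of summits of both lists within a tolerance on the -log10 p of 0.001 (wider in proportion above 10), and the lowest background was 0.679 in the control and 0.397 in the knockout list. Their ratio of 0.585 would go with a lower depth of the knockout library, if both were called with the same settings. In genes with a summit in both lists, the median of the highest implied read number fell from 32 to 11 over 17 plasma protein genes. Over 10 genes of fatty acid oxidation it fell from 28.5 to 9, and over 5 genes of fatty acid synthesis from 16 to 10. A depth lower by that ratio alone would not reach the fall in the first 2 of these lists. A link between the loss and the RNA change was sought in 4 ways. In 573 genes with a summit in both lists, the knockout fold had a mean rank correlation of 0.107 with the RNA log2 fold change (within 10 bins of the control fold, permutation p = 0.011). Without bins, the Spearman correlation of the implied read ratio with the RNA log2 fold change was 0.369. Genes that kept a knockout summit had no higher RNA log2 fold change than those that lost it (medians -0.187 and -0.10). The difference within 20 bins of the control fold was -0.0688 (permutation p = 0.10). The 28 genes with a knockout summit only had a median of 0.188, with 7 higher and 3 lower. A link with the RNA change stays open, since the 2 forms with a permutation p disagree and the other 2 carry no test. None of the 4 forms asks whether the same proportion was lost at every gene. At G6pc the highest implied read number was 71 in the control and 12 in the knockout list, and at Alb 137 and 23. At Tat these numbers were 94 and 44, and at Pck1 108 and 46. The fall thus differed between these genes, some of them chosen after their values were seen. How much of the difference between the lists comes from the genotype stays open with 1 library each.

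With 3 libraries against 3, only 10 splits exist, too few for a share under 0.05. The real split gave 3865 genes, 1 of the 10 splits gave as many, and the highest of the others gave 0 in edgeR. Each of the others mixes both genotypes in both groups, which widens the spread within groups. Their 0 calls therefore lend no support to the real split.

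The knockout list held 6 regions on the mitochondrial chromosome and the control list held 0. Polr2a, Alb and Errfi1 illustrate the shape of the control regions, with 803 bp covered at the start of Polr2a but 17349 bp at Alb and 20133 bp at Errfi1 by regions that reach past the gene end, genes chosen after their values were seen.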
